A study of Mus musculus with 36 samples.

How the data were processed

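RNA of 18 mouse hearts was measured on 2 Affymetrix chips each, 430A and 430B, after isolation with the Ultraspec(TM)-II RNA Isolation System and biotin labelling by the manufacturer's procedures, per the labels. The hearts fall into 5 groups by the state of the Akt1 transgene, 3 groups of 4 hearts and 2 groups of 3. The deposited values were linear intensity values, the MAS5 signal per probe set according to the submitters' processing notes, whose version is not given in the sources used here. The 2% trimmed means of the arrays of a chip deviated from their mean by at most 0.006% on chip 430A (mean 500.2) and 0.00369% on chip 430B (mean 122.5), which shows that each array had been scaled to a common level before deposit. The signals were therefore used as deposited. Scan dates and batches are not given in the sources used here, so no batch could be tested, and detection calls were not analysed here. Arrays have no depth in counts, and the number of arrays limits the precision.

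Chip 430A held 22690 probe sets and chip 430B 22575, of which 64 on each were control probe sets and were left out of the model. Gene symbols came from the annotation of the platform. On chip 430A 20380 probe sets had 1 symbol, 691 several and 1555 none, and on chip 430B the numbers were 14661, 245 and 7605. Probe sets were kept if their mean signal over all 18 arrays was at least 20% of the trimmed mean, which left 15565 on chip 430A and 17519 on chip 430B, standing for 14650 genes. No genome coordinates were used.

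Signals were log2-transformed after adding an offset of 10% of the trimmed mean (50.02 on chip 430A, 12.25 on chip 430B). Each chip was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) with 1 mean per group and all 18 arrays sharing 1 spread. The 7 comparisons were contrasts of those means, p-values were adjusted by the Benjamini-Hochberg method within a chip, and a probe set was called at an adjusted p under 0.05. Log2 changes carry the standard error of that model, and signals are given as mean ± SD of the deposited values. The labels describe individual mice, and the p-values measure the spread between these hearts. Simulated data with known changes held independent noise and 200 changed probe sets per chip. There the model recovered 64.2% to 85.1% of the changes of 1 log2 unit on chip 430A and 22.4% to 47.8% on chip 430B. At 0.5 log2 units it recovered 9.0% to 22.4% and 0% to 6.0%. At most 10.7% of the calls were false in any simulated comparison, each drawn 1 time. The real number of changes is not known, so these rates may not carry over. The joint counts of reversed and shared calls were set beside independent lists, simulated groups with no change, and divisions of the shared hearts.

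The comparisons, their tests of probe sets and lists, and the 26 gene lists were fixed before the data were examined, while some tests of explanations came later. The lists covered the hypertrophy and fetal program, adult sarcomere, fatty acid use, mitochondrial gene regulators, oxidative phosphorylation, tricarboxylic acid cycle, glycolysis and glucose uptake, extracellular matrix, angiogenic growth factors, calcium handling, ion channels and gap junctions, translation, FoxO and atrophy targets, insulin and PI3-kinase signalling, proliferation, unfolded protein response, immediate early and handling genes, and natriuretic and wall stress genes of failure. Further lists held markers of endothelium, fibroblasts, macrophages and leukocytes, smooth muscle and pericytes, atria, adipocytes, erythroid cells, and nerve and Schwann cells. Each list was tested against the other genes with limma's camera at a preset correlation of 0.01 on the genes of chip 430A, adjusted over the lists of a comparison, and the test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance one way. Members called were counted over both chips. Median, mean and test had the same sign for each list that camera called. A score per heart, the mean difference of a list's genes from the hearts before induction, was compared between groups with two-sided exact permutation tests, whose smallest p was 0.0286, or 0.1 for 3 against 3 hearts, and whose lowest adjusted p was 0.093.

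For 5 main comparisons the named genes were the 6 with the largest rise and the 6 with the largest fall on chip 430A and 2 and 2 on chip 430B, among called probe sets with 1 symbol whose hearts did not overlap between the groups. To these came up to 4 called members of each list by adjusted p, and Akt1. Genes named for their largest changes are given by the probe set with that change. Otherwise, for a gene with several probe sets the brightest stood for it, on chip 430A where possible, and opposite calls of its other probe sets are stated. Xist, the Y-linked genes and the genes that set repressed hearts apart were chosen after their values were seen, and the clock genes after the repressed hearts had been seen to stand apart but before their own values were seen.

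RNA quality was read from the 3′ to 5′ signal ratios of the Actb and Gapdh control probe sets and the signal of 18S ribosomal RNA, compared between groups with two-sided exact permutation tests, those of 18S added after the data were seen. The alternatives tried were no offset and an offset of 20%, quantile normalization and scaling to a common median, no filter and a filter of 50%, only the arrays of the 2 groups compared, no trend, array weights, a change of at least 2-fold, the replicate number as a block, leaving out each heart in turn, the mean of all probe sets of a gene for the lists, an estimated correlation and fry. After the data were seen, 3 more were added: leaving out hearts 3 and 4 before induction, an indicator of high Xist signal as a covariate, and the Actb ratio as a covariate. The 50% filter and the 20% offset were added then for the lists as well. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.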

Results

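The hearts came from mice with a cardiac, tetracycline-controlled Akt1 transgene. Akt1 is a kinase downstream of insulin and growth factor receptors that drives growth of heart muscle cells, and the myristoylated form encoded by the transgene is held at the membrane in an active state. RNA of 18 hearts was hybridised to 2 Affymetrix chips, 430A and 430B, giving 36 arrays. There were 4 hearts before induction at 12 weeks of age, 4 after 2 weeks of induction at 14 weeks, and 4 with a further 2 days of repression. A group of 3 hearts was taken after 6 weeks of induction at 18 weeks of age, and another of 3 after 2 more weeks of repression at 20 weeks. Age rose with the time of induction, and the repressed hearts, at 14 weeks and 2 days and at 20 weeks, were older than the induced hearts they are compared with. Median signals per array ran from 183 to 231.7 on chip 430A and from 60.9 to 78.9 on chip 430B. The number of arrays limits the precision.

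Hearts 3 and 4 of the group before induction, labelled male like all others, had signals of 2518 and 2170 for 1 of the Xist probe sets, against 4.4 to 92.8 in the other 16 hearts. Heart 3 of the 6-week induction had an Actb 3′ to 5′ signal ratio of 3.71 on chip 430A, where the mean of that group was 2.10 ± 1.39 (SD, n = 3). The ratio was 1.38 ± 0.165 before induction, 1.47 ± 0.305 at 2 weeks on and 1.09 ± 0.0609 at 2 days off (SD, n = 4 each), and 1.10 ± 0.134 at 2 weeks off (SD, n = 3). The Actb ratio was lower on both chips in each heart at 2 days off than in the hearts at 2 weeks on and before induction (exact p = 0.0286 each, the smallest these group sizes allow). Adjusted over 28 tests those p values became 0.16, and so many tests at that smallest p leave little room to pass. The signal of 18S ribosomal RNA on chip 430A was 244 ± 74.4 before induction, 154 ± 36.7 at 2 weeks on and 81.2 ± 26.2 at 2 days off (SD, n = 4 each), and 43.2 ± 26 at 6 weeks on and 49.6 ± 3.61 at 2 weeks off (SD, n = 3 each). The values before induction lay above those at 2 days off, 6 weeks on and 2 weeks off without overlap (exact p = 0.0286 each, and 0.05 adjusted over 14 tests).

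The first comparison asked which transcripts differ after 2 weeks of Akt1 induction, the stage of early growth. Of 3 Akt1 probe sets, 1 on chip 430A rose from a signal of 547.8 ± 69.7 to 2878 ± 645 (SD, n = 4 each), a log2 change of 2.27 ± 0.161 (SE; adjusted p = 7.94e-08). The other Akt1 probe sets were not called, with log2 changes of -0.23 on chip 430A and -0.63 on chip 430B, and values of Akt1 given hereafter are from the first. Which of them match the transgene is not given in the sources used here, so these values do not separate its transcript from that of the mouse gene. More genes of the extracellular matrix (21 of 30) and of proliferation (11 of 22) rose than fell, and more targets of FoxO, the transcription factors that Akt inhibits, fell (5 of 20) than rose (1). These list calls ended with an estimated correlation between genes (adjusted p = 0.0619, 0.0821 and 0.0675). Over both chips 1658 of 33084 probe sets were called, 881 higher and 777 lower, which stood for 1293 genes.

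Of 30 measured extracellular matrix genes, 21 rose and 0 fell (25 and 0 adjusted over the list alone). Postn, a matricellular protein of remodelling tissue, rose from 695 ± 206 to 6287 ± 1355 (log2 3.11, adjusted p = 7.94e-08). Col8a1 rose by 1.69, Col5a2 by 1.40 and Vcan, the proteoglycan versican, by 1.10 on the log2 scale. Cilp, a matrix protein first known from cartilage, rose from 325.7 ± 145 to 1971 ± 566 on chip 430B (log2 2.61). The camera test gave the matrix list an adjusted p of 2.01e-21 (adjusted p = 0.0619 with an estimated correlation). Proliferation genes numbered 11 higher and 0 lower of 22 (12 and 0 adjusted over the list alone; adjusted p = 7.02e-10, and adjusted p = 0.0821 with an estimated correlation). Mcm6, a subunit of the replication helicase, rose from 18.8 ± 4.74 to 386.2 ± 41.7 (log2 2.66), Mki67 rose by 1.73, Ccnb2 by 1.78 and Top2a by 1.27. The signals of Mcm6 and Ccnb2 before induction lay below the offset of 50.02, so the size of their log2 changes depends on it.

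FoxO and atrophy targets gave 1 gene higher and 5 lower of 20 (1 and 5 adjusted over the list alone; adjusted p = 0.00217, and adjusted p = 0.0675 with an estimated correlation). Fbxo32, the atrophy ubiquitin ligase atrogin-1, fell from 1729 ± 668 to 501.3 ± 34.8 (log2 -1.62). Klf15, a transcription factor that restrains cardiac growth, fell from 527 ± 77 to 108.4 ± 47 (log2 -1.90), and Gabarapl1, an autophagy protein, had a log2 change of -0.81. In the insulin and PI3-kinase list, of 17 genes 1 rose (Akt1 itself) and 4 fell (2 and 5 adjusted over the list alone). Irs1, the insulin receptor substrate, had a log2 change of -1.29, Akt2 of -0.72 and Tsc2, an inhibitor of mTORC1, of -0.80. That list as a whole did not pass (adjusted p = 0.412).

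Metabolic genes moved in both directions. Of 12 regulators of mitochondrial genes 0 rose and 3 fell (0 and 4 adjusted over the list alone; list adjusted p = 0.0868): Ppara by log2 -1.53, Esrrb by -1.03 and the coactivator Ppargc1a by -0.81. That list was called without the hearts with Xist signal (adjusted p = 0.0459), with an Xist indicator (0.0437), and without heart 4 before induction (0.0421) or heart 1 (0.0338) or heart 3 (0.0488) at 2 weeks. Of 27 genes of fatty acid uptake and oxidation 4 rose and 4 fell (4 and 6 adjusted over the list alone), among them Slc25a20, the carnitine carrier, at 1.25 and Pdk4, which inhibits pyruvate dehydrogenase, at 1.30. The glucose transporters Slc2a4 and Slc2a1 had log2 changes of -0.80 and -0.92, in a glycolysis list with 3 genes higher and 2 lower of 19 (4 and 2 adjusted over the list alone). The tricarboxylic acid cycle list had 1 higher and 4 lower of 16 (1 and 5 adjusted over the list alone), with Idh2 at -0.80, and oxidative phosphorylation had 0 and 2 of 54 (0 and 2 adjusted over the list alone), Ndufs1 at -0.59 and Ndufv1 at -0.51.

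The largest falls were in Myom2, a protein of the sarcomere M-band, from 4649 ± 1497 to 264.9 ± 155.5 (log2 -4.01), Doc2g at -3.04, the prostaglandin D synthase Ptgds at -2.63, the G protein subunit Gnb3 at -2.14 and the carboxylesterase Ces1d at -1.94. On chip 430B Kcnip2, a subunit of the transient outward potassium channel, had a log2 change of -3.58. Trdn, which anchors the calcium release channel, had the largest rise on the log2 scale with its offset (3.80), while another Trdn probe set was called lower. By the ratio of mean signals Mcm6 rose more, 20.51 against 17.74 for Trdn. Ryr1, the skeletal muscle form of that channel, rose by 2.59, the skeletal myosin light chain Myl1 by 2.42, Sh3gl3 by 2.60 and the basement membrane collagen Col4a4 by 2.32 on chip 430B.

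Of 12 ion channel and gap junction genes 0 rose and 3 fell (0 and 3 adjusted over the list alone), with Gja1, connexin 43, at -0.65 and Kcnq1 at -0.68. Of 13 calcium handling genes 2 rose and 1 fell (3 and 2 adjusted over the list alone): Ryr2 at 0.90, Casq2 at 0.69 and phospholamban, Pln, at -0.39. In the 19 adult sarcomere genes Pdlim5 rose by 0.42 and Myom2 fell (1 and 1 adjusted over the list alone), and the list was called without heart 1 at 2 weeks (adjusted p = 0.0412). Among the angiogenic growth factors 0 of 14 rose and 1 fell, Vegfb at -0.84, with the same counts adjusted over the list alone. The natriuretic and wall stress list had 1 higher and 0 lower of 8 (3 and 1 adjusted over the list alone), Timp1 at 1.68, and the hypertrophy and fetal list 0 and 0 of 10 (0 and 0 adjusted over the list alone).

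Among the markers of other cell types, those of fibroblasts had the most calls. Fibroblast markers had 3 higher and 1 lower of 13 (4 and 1 adjusted over the list alone), with Mfap5 at 1.14 and Pi16 at 0.83. Endothelial markers had 1 and 0 of 22 (0 and 0 adjusted over the list alone), Cldn5 at 0.59, and smooth muscle and pericyte markers 0 and 1 of 12 (0 and 1 adjusted over the list alone), Abcc9 at -0.93. Adipocyte markers had 1 and 0 of 6 (1 and 0 adjusted over the list alone), the lipogenic enzyme Fasn at 1.42. Counts were 0 and 0 for 21 macrophage and leukocyte, 6 atrial, 2 erythroid and 4 nerve and Schwann cell markers, and adjusted over the list alone the nerve list had 1 lower. Translation and ribosome biogenesis had 0 and 1 of 23, Eef2 at -0.41; the unfolded protein response 1 and 0 of 17, Manf at 0.85; and immediate early and handling genes 1 and 0 of 15, Gadd45g at 1.04, each with the same counts adjusted over the list alone.

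The count fell to 1019 without heart 3 before induction, to 1035 without heart 3 of the 2-week induction, and to 524 without both hearts with Xist signal, where leaving out any other pair of the 4 gave 465 to 1038. Arrays scaled to a common median gave 923 higher and 590 lower, a share higher of 61% against 53.1%. Other splits of the same 8 hearts called up to 357 probe sets and up to 10 of the 26 lists, against 3 for the real one.

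**Figure D1:**
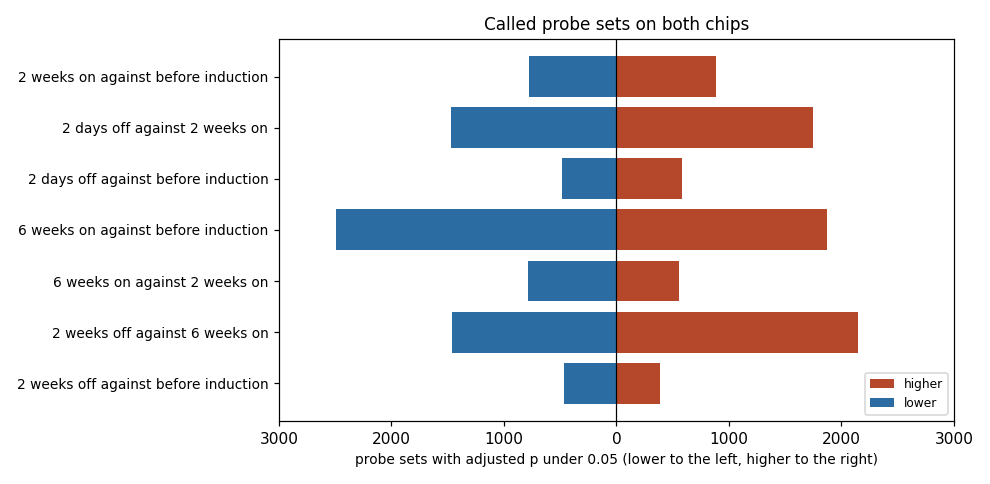
Number of called probe sets on both chips in each of the 7 comparisons, those higher in the first-named group to the right and those lower to the left. The 6-week comparison with the hearts before induction has the most calls, 4361, and the comparison of 2 weeks off with before induction the fewest, 851.

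The next comparison asked how the 2-week pattern changed within 2 days of switching the transgene off. Akt1 fell from 2878 ± 645 to 718 ± 21.8 (SD, n = 4 each; log2 -1.90, adjusted p = 6.23e-07), and 6 of 20 FoxO targets rose while 4 of 22 proliferation genes fell. Both list calls ended with an estimated correlation (adjusted p = 0.0563 and 0.562). Myom2 rose from 264.9 ± 155.5 to 3644 ± 1012 (log2 3.67), and desmoplakin, Dsp, which anchors desmosomes, rose by 3.22. Of several probe sets, a dimmer 1 of Gja1 rose by 2.90 and a dimmer 1 of Ryr2, the cardiac calcium release channel, by 2.49. The brightest probe set of Gja1 rose by 0.57, and that of Ryr2 was already higher by 0.90 at 2 weeks on against before induction. Psmd6, a proteasome regulatory subunit, fell from 1240 ± 323 to 66.9 ± 17.6 (log2 -3.44). Of 33084 probe sets 3219 were called, 1749 higher and 1470 lower, for 2348 genes.

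FoxO and atrophy targets gave 6 genes higher and 1 lower of 20 (9 and 1 adjusted over the list alone; adjusted p = 0.000412, and adjusted p = 0.0563 with an estimated correlation). Fbxo32 rose to 2002 ± 321 (log2 1.88), Klf15 to 449 ± 72.8 (log2 1.69) and Gabarapl1 to 2638 ± 400 (log2 1.36), and Trim63, the ubiquitin ligase MuRF1, rose by 0.88. In the insulin and PI3-kinase list 3 genes rose and 2 fell of 17 (3 and 2 adjusted over the list alone; list adjusted p = 0.444), with Irs1 at 1.06, Tsc2 at 0.92 and Akt2 at 0.55. Of 22 proliferation genes 0 rose and 4 fell (0 and 5 adjusted over the list alone; adjusted p = 0.000763, and adjusted p = 0.562 with an estimated correlation), Mcm6 by log2 -1.87 and Mki67 by -1.03. The call of that list ended with a filter at 50% of the trimmed mean (adjusted p = 0.163).

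Oxidative phosphorylation had 2 genes higher and 14 lower of 54 (2 and 17 adjusted over the list alone; adjusted p = 7.78e-07, and adjusted p = 0.562 with an estimated correlation; 0.131 with quantile normalization). Ndufb10 of complex I had a log2 change of -0.90, Ndufc2 of -0.73 and cytochrome c, Cycs, of -0.78, while Sdha of complex II rose by 0.47. Regulators of mitochondrial genes had 3 higher and 0 lower of 12 (4 and 0 adjusted over the list alone; list adjusted p = 0.262), Ppara at 1.22 and Perm1 at 0.85. Slc25a20 at -1.57 and Pdk4 at -1.29 were among the 7 genes of fatty acid use that fell, with 3 that rose, of 27 (3 and 7 adjusted over the list alone). Slc2a4 rose by 0.97 and Slc2a1 by 0.74.

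Angiogenic growth factors had 3 higher and 0 lower of 14 (5 and 1 adjusted over the list alone; adjusted p = 0.0374, and adjusted p = 0.292 with an estimated correlation): Vegfb at 0.69, Vegfa at 0.61 and the matricellular Ccn1 at 0.75. The call ended without the filter on dim probe sets (adjusted p = 0.0581), without heart 2 (0.0846) or heart 3 (0.0521) of the 2-week induction and without heart 1 of the repressed group (0.0659). Macrophage and leukocyte markers had 2 higher and 0 lower of 21 (0 and 0 adjusted over the list alone; adjusted p = 0.0301, and adjusted p = 0.562 with an estimated correlation), Lyz2 at 0.73 and Tyrobp at 0.58, and that call ended with the Actb ratio as a covariate (adjusted p = 0.135) and without heart 1 (0.0659) or heart 3 (0.0908) of the repressed group. Nppb, which encodes the natriuretic peptide BNP, rose from 1593 ± 408 to 5464 ± 1110 (log2 1.76, adjusted p = 0.0041), and Ankrd1, a stretch-responsive sarcomere protein, rose by 0.74. Marker scores of atrium and fat were higher by 1.28 (exact p = 0.229) and 1.35 (exact p = 0.143), and the atrial score ran from -0.83 to 2.47 between the repressed hearts. Such scores can depend on dissection, which was not tested. The potassium channel genes Kcnj11, Kcnj5 and Hcn2, a pacemaker channel, rose by 1.16, 1.16 and 0.68, in an ion channel list with 4 higher and 2 lower of 12 (5 and 2 adjusted over the list alone; list adjusted p = 0.0964).

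The extracellular matrix list had 0 higher and 2 lower of 30, Vcan at -0.64 and Postn at -0.66 (0 and 1 adjusted over the list alone; list adjusted p = 0.717). The chaperones of the endoplasmic reticulum Manf, Hsp90b1 and Hspa5 had log2 changes of -0.87, -0.63 and -0.69, in an unfolded protein response list with 0 higher and 3 lower of 17 (0 and 3 adjusted over the list alone; list adjusted p = 0.315). Other large rises were in glycogen synthase, Gys1, at 2.63, its phosphatase subunit Ppp1r3c at 2.47 and Arhgap26 at 2.97 (chip 430B). Other large falls were in the transferrin receptor Tfrc at -2.65, the tubulins Tuba4a at -2.73, Tubb6 at -2.10 and Tubb4b at -2.03, Trdn at -2.29 with another of its probe sets called higher, and on chip 430B Pih1d1 at -3.08 and Nxpe4 at -3.00. With arrays scaled to a common median, 1446 probe sets were higher and 1820 lower, so the share higher went from 54.3% to 44.3%. Other splits of these hearts called at most 2 probe sets, and up to 10 lists against 5 for the real one.

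Some lists were called after 2 days off only with other settings. The tricarboxylic acid cycle list was called with quantile normalization (adjusted p = 0.000805), and the endothelial list without heart 2 at 2 weeks on (0.0194) or heart 3 of the repressed group (0.0215). Without heart 4 at 2 weeks on the sarcomere (0.0209), fatty acid (0.0205) and immediate early (0.00565) lists were called, and without heart 4 of the repressed group the atrial (0.0338) and adipocyte (0.0203) lists.

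A share of the 2-week changes moved back towards the hearts before induction. Of the 1658 probe sets called at 2 weeks, 821 (49.5%) were called with the opposite sign after 2 days off, 441 of them lower at 2 weeks, Myom2, Fbxo32, Irs1 and Slc2a4 included, and 380 higher, Mcm6 and Pdk4 included. Independent lists would share 39.1 of those higher and 41.1 of those lower. Both comparisons used the same hearts at 2 weeks. In 50 simulations of groups with no change the mean reversed count was 0.02. Without a change there are almost no calls to reverse, so that count cannot show what the shared hearts contribute. The log2 changes of the comparisons on the A chip had a correlation of -0.643, against a mean of -0.501 in those simulations. Shared hearts alone set a correlation near that mean, so it does not measure their part. The covariance of the changes was -0.1034, against a mean of -0.0211 in the simulations. With the 2-week hearts divided between the comparisons in 6 ways, 178 to 219 were reversed, 26.7% to 38.6% of those called. Of the 1658, 264 (15.9%) were still called with the same sign against the hearts before induction. Without heart 3 of the 2-week induction 477 were reversed, without the hearts with Xist signal 275, with an Xist indicator 303, with array weights 1900 and with a minimum of 2-fold 139.

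Hearts at 2 days off were also compared with those before induction. The matrix list was still higher, with 18 genes higher and 0 lower of 30 (28 and 0 adjusted over the list alone; adjusted p = 1.78e-24, and adjusted p = 0.0377 with an estimated correlation). Postn stood at 3909 ± 512 against 695 ± 206 before induction (SD, n = 4 each; log2 2.45, adjusted p = 2.11e-06), Col5a2 was higher by 1.45 and Lox, which crosslinks collagen, by 1.17. Akt1 did not pass (log2 0.37, adjusted p = 0.196). In all, 1069 probe sets were called, 585 higher and 484 lower, for 816 genes. Ryr2, by its brightest probe set, was higher by 1.06, and Tcap, a sarcomere Z-disc protein, had a log2 change of -0.77.

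Of the 10 lists called there, 9 were lost with an estimated correlation. Oxidative phosphorylation had 0 higher and 7 lower of 54 (0 and 14 adjusted over the list alone; adjusted p = 1.65e-10, and adjusted p = 0.525 with an estimated correlation; 0.117 with quantile normalization), Ndufb10 at -0.85 and Cox8b at -0.65. Macrophage and leukocyte markers had 1 and 0 of 21 (6 and 0 adjusted over the list alone; adjusted p = 0.000184, and adjusted p = 0.525 with an estimated correlation), H2-Eb1 at 0.86. Proliferation had 3 and 0 of 22 (4 and 0 adjusted over the list alone; adjusted p = 0.00697, and adjusted p = 0.526 with an estimated correlation), Cdk1 at 1.29. The natriuretic list had 2 and 0 of 8 (2 and 1 adjusted over the list alone; adjusted p = 0.0233, and adjusted p = 0.373 with an estimated correlation), Ace at 1.01 and Timp1 at 1.92. Adult sarcomere (0.0233), hypertrophy and fetal (0.0321), angiogenic growth factor (0.0321), adipocyte (0.0321) and fatty acid (0.0387) lists had the adjusted p values given, and with an estimated correlation adjusted p values of 0.653, 0.526, 0.335, 0.547 and 0.526. The median of the fatty acid list turned from -0.10 to 0.02 with quantile normalization, which ended its call (adjusted p = 0.996) and that of the sarcomere list (0.756).

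Several of these calls ended with other settings. The filter at 50% of the trimmed mean ended those of proliferation (adjusted p = 0.34), hypertrophy and fetal (0.0656), adipocyte (0.121) and fatty acid genes (0.153). The natriuretic and the hypertrophy and fetal calls ended without the hearts with Xist signal (0.0833 and 0.486), with an Xist indicator (0.0985 and 0.581) and with the Actb ratio as a covariate (0.0857 and 0.0523). Atrial markers, with a mean log2 change of 1.27, were called without the hearts with Xist signal (0.00121), with an Xist indicator (0.00577), and without heart 4 before induction (0.0037) or of the repressed group (0.0273), and not with all hearts (0.21). Endothelial (0.0466) and translation genes (0.0359) were called without the hearts with Xist signal too, translation also with the indicator (0.035) and without heart 4 before induction (0.0396). Quantile normalization added the tricarboxylic acid cycle (0.0243) and calcium handling (0.0399) lists. The Xist indicator also ended the proliferation (0.0507), fatty acid (0.0507) and angiogenic calls (0.0632), and the Actb ratio the sarcomere (0.0925) and adipocyte calls (0.0523). No filter ended the angiogenic call (0.0878) and no offset the adipocyte call (0.0579).

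Single hearts mattered too. Without heart 1 before induction the sarcomere (adjusted p = 0.411), fatty acid (0.211) and adipocyte (0.0742) calls ended, without heart 2 the hypertrophy and fetal and the adipocyte calls (0.0727 each), and without heart 4 the angiogenic call (0.0861). The immediate early list was called without heart 2 before induction (0.0405). Without heart 3 before induction the hypertrophy and fetal (0.223), fatty acid (0.0876), adipocyte (0.0766) and natriuretic (0.0811) calls ended. Without heart 1 of the repressed group the hypertrophy and fetal (0.0796), sarcomere (0.0846), fatty acid (0.115) and angiogenic (0.0796) calls ended, without heart 2 the adipocyte call (0.0618), and without heart 3 the fatty acid (0.0556), adipocyte (0.201) and proliferation (0.0556) calls.

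The count of 1069 fell to 601 without heart 2 and 526 without heart 3 before induction, and to 570, 502 and 531 without hearts 1, 2 and 4 of the repressed group. It was 509 without the hearts with Xist signal, where leaving out other pairs gave 145 to 698. Arrays scaled to a common median gave 600 higher and 437 lower, and other splits called at most 2 probe sets and up to 10 lists, as many as the real one.

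**Figure D2:**
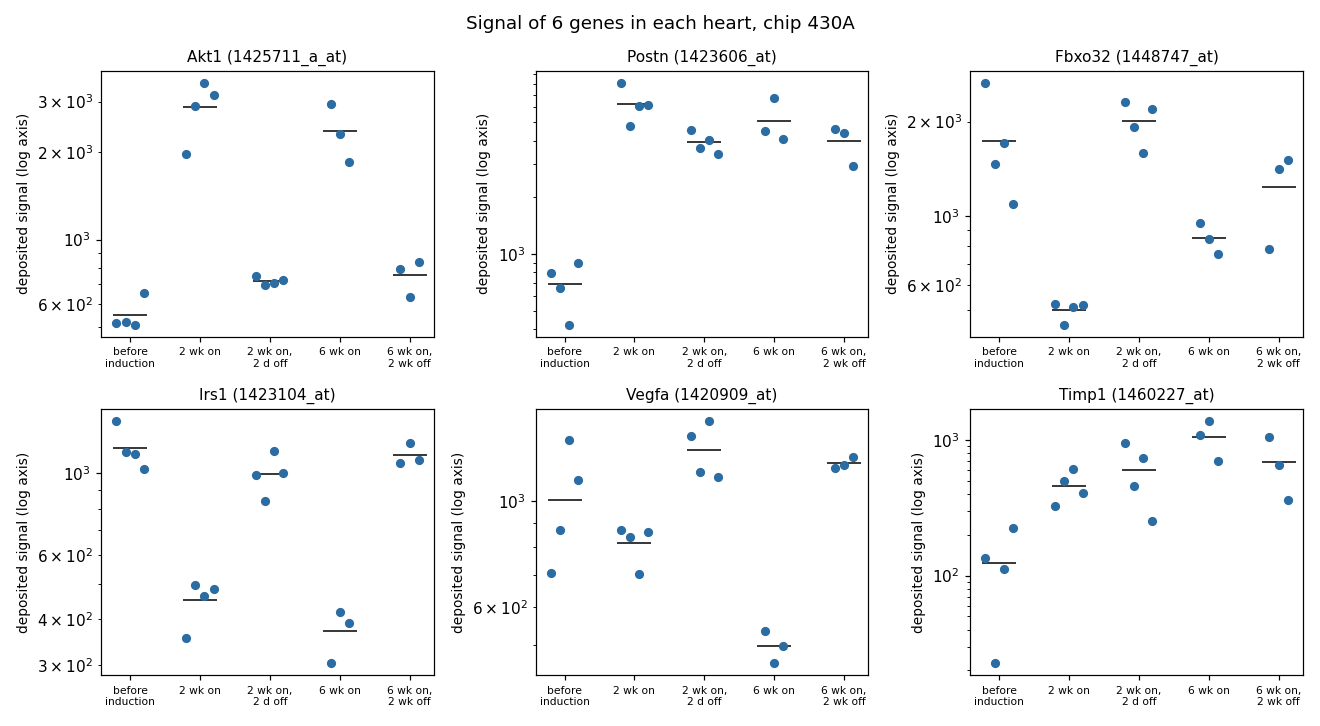
Deposited signal on a log axis of 6 genes in each heart (points) by group, with a bar at the group mean. Akt1 is high in both induced groups, Postn stays above its level before induction in all 4 later groups, and Fbxo32 and Irs1 are low in both induced groups.

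The comparison of 6 weeks of induction with the hearts before it addressed the later stage, which the series ties to heart failure. Akt1 stood at 2365 ± 542 (SD, n = 3) against 547.8 ± 69.7 (SD, n = 4; log2 2.00, adjusted p = 7.3e-07), while the other Akt1 probe set of chip 430A had a log2 change of -0.54 (adjusted p = 0.0236). More matrix genes (19 of 30) rose than fell, as did 5 of 8 genes of the natriuretic and wall stress list, though not the natriuretic peptide gene Nppb (log2 0.07, adjusted p = 0.917), 18 of 54 genes of oxidative phosphorylation fell and 1 rose, and Myom2 and Vegfa fell. These list calls ended with an estimated correlation (adjusted p = 0.0986, 0.0986 and 0.809). Over both chips 4361 probe sets were called, 1868 higher and 2493 lower, for 3220 genes. The median change of all chip 430A probe sets was -0.11, and -0.01 with arrays scaled to a common median, which gave 2409 higher and 1646 lower and moved the share higher from 42.8% to 59.4%.

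The matrix list had 19 higher and 0 lower of 30 (24 and 0 adjusted over the list alone; adjusted p = 3.67e-15, and adjusted p = 0.0986 with an estimated correlation), with Postn at 5085 ± 1407 (log2 2.80), Col5a2 at 1.38 and the growth factor Tgfb2 at 1.44. Of the 8 natriuretic and wall stress genes 5 rose and 0 fell (5 and 0 adjusted over the list alone; adjusted p = 0.000248, and adjusted p = 0.0986 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose from 122.9 ± 82.2 to 1051 ± 337 (log2 2.77), angiotensinogen, Agt, by 2.51, angiotensin converting enzyme, Ace, by 1.35 and Lcn2 by 1.60. The fifth was Ccn2, which the hypertrophy and fetal list also holds, and Timp1 is in the matrix list as well. The hypertrophy and fetal list had 4 higher and 0 lower of 10 (5 and 0 adjusted over the list alone; adjusted p = 0.0156, and adjusted p = 0.666 with an estimated correlation), among them Myh7, the fetal myosin heavy chain, at 1.69 and Ccn2, a matricellular growth factor, at 1.57. That call ended without the hearts with Xist signal (adjusted p = 0.16), with an Xist indicator (0.209), without heart 3 before induction (0.0829) and without heart 2 at 6 weeks (0.0764).

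Oxidative phosphorylation had 1 gene higher and 18 lower of 54 (1 and 22 adjusted over the list alone; adjusted p = 0.00523, and adjusted p = 0.809 with an estimated correlation). Ndufs1 fell from 7122 ± 264 to 3496 ± 900 (log2 -1.05), Ndufv1 by log2 -0.87 and Sdhc by -0.71. The tricarboxylic acid cycle list had 0 and 5 of 16 (0 and 6 adjusted over the list alone; adjusted p = 0.0452, and adjusted p = 0.666 with an estimated correlation), Suclg2 at -1.18 and Idh2 at -1.06. Arrays scaled to a common median ended both calls (adjusted p = 0.0511 and 0.169), as did leaving out heart 1 before induction (0.374 and 0.331) or heart 2 at 6 weeks (0.19 and 0.171). The cycle list was also lost with the Actb ratio as a covariate (0.0784) and without heart 3 before induction (0.0829), heart 3 at 6 weeks (0.126), heart 2 at 2 weeks on (0.0523), or hearts 1 (0.0526) or 2 (0.0506) at 2 weeks off. Ppargc1a had a log2 change of -1.13 and Esrrb of -1.14, while Esrra rose by 0.55, in a regulator list with 1 higher and 3 lower of 12 (2 and 3 adjusted over the list alone; list adjusted p = 0.386). Pdk4 rose from 1958 ± 626 to 9217 ± 3425 (log2 2.18), and Slc27a1, a fatty acid transporter, had a log2 change of -1.19.

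Of 14 angiogenic growth factors 1 rose, Vegfd at 1.89, and 7 fell (1 and 7 adjusted over the list alone; list adjusted p = 0.386), Vegfa from 1004 ± 275 to 497.4 ± 38.3 (log2 -0.91), Vegfb by log2 -1.02 and Apln, the ligand of the apelin receptor, by -0.72. Endothelial markers had 1 higher and 5 lower of 22 (1 and 5 adjusted over the list alone; list adjusted p = 0.319), Emcn at -1.17, Pecam1 at -1.02 and the transcription factor Erg at -1.11. That list was called without the hearts with Xist signal (adjusted p = 0.0304) and with an Xist indicator (0.0308). Pericyte markers moved both ways, Abcc9 and Kcnj8, which form a potassium channel, at -2.77 and -0.94 and Cnn1 and Cspg4 at 1.96 and 0.56. Casq2 rose by 1.06, Pln had a log2 change of -0.71 and Gja1, by its brightest probe set, of -1.03. Irs1 stood at 370.8 ± 59.5 (log2 -1.54), and Fbxo32 and Trim63 had log2 changes of -0.92 and -0.74, in a FoxO list with 1 higher and 3 lower of 20 (1 and 3 adjusted over the list alone; list adjusted p = 0.986). Proliferation had 2 higher and 1 lower of 22 (0 and 1 adjusted over the list alone; list adjusted p = 0.386), with Pcna, the clamp of DNA replication, at -0.72.

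The largest rises were in Trdn at 4.41, Thbs4, a matricellular thrombospondin, at 4.08, Ryr1 at 3.80, Ints6 at 3.43, the cell cycle inhibitor Cdkn1a at 3.24, the mitochondrial folate enzyme Mthfd2 at 3.22 and Cilp at 3.41. The largest falls were in Doc2g at -3.35, Abcc9 at -2.77, Ttll1 at -2.62, Gnb3 at -2.49, Gja1, by another probe set, at -2.42 and Myh6, the adult cardiac myosin heavy chain, at -2.49 with an adjusted p of 0.0486. On chip 430B Orai3, a store-operated calcium channel, had a log2 change of -3.16. Gadd45g, a stress-induced gene, rose by 2.43, Alas2, a marker of red cell precursors, had a log2 change of -1.74, and Mbp, a myelin protein, of -1.05. Without heart 3 at 6 weeks, the heart with the Actb ratio of 3.71, 3111 probe sets were called, 2585 of them among the 4361. Without the hearts with Xist signal the count was 2115, where leaving out other pairs gave 2006 to 3292, and other splits of these 7 hearts called up to 2100 probe sets and up to 12 lists against 5 for the real one. The split with 2100 set hearts 2, 3 and 4 before induction against heart 1 and all 6-week hearts, so it kept much of the real grouping.

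Calls at 2 and at 6 weeks overlapped. Of the 1658 probe sets called at 2 weeks, 1031 (62.2%) were called with the same sign at 6 weeks, 564 higher, Postn and Mcm6 included, and 467 lower, Irs1 and Myom2 included, and 7 had opposite signs. Independent lists would share 49.7 higher and 58.6 lower. The hearts before induction served both comparisons. Simulated groups with no change gave a mean shared count of 0 in 50 simulations. Without a change there are almost no calls to share, so that count cannot show what the shared controls contribute. The correlation of the log2 changes on the A chip was 0.668, against a mean of 0.465 in those simulations. Shared controls alone set a correlation near that mean, so it does not measure their part. The covariance of the changes was 0.1209, against a mean of 0.0212 in the simulations. With the 4 control hearts divided between the comparisons in 6 ways, 273 to 414 were shared, 39.9% to 58.7% of those called. Without heart 3 before induction the number shared was 648, without the hearts with Xist signal 349, with an Xist indicator 368, with array weights 1601 and with a minimum of 2-fold 227.

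The induced groups were then compared directly, 6 weeks with 2 weeks. Akt1 did not differ by the test (2365 ± 542, n = 3, against 2878 ± 645, n = 4; SD; log2 -0.27, adjusted p = 0.388 by limma). Of the natriuretic, the hypertrophy and fetal and the FoxO lists 3 of 8, 4 of 10 and 3 of 20 genes were higher at 6 weeks, and of the proliferation, endothelial and oxidative phosphorylation lists 7 of 22, 6 of 22 and 6 of 54 were lower. These list calls ended with an estimated correlation (adjusted p = 0.0525, 0.539, 0.0525, 0.267, 0.683 and 0.683). Myh7 stood at 5635 ± 2416 against 993.2 ± 309 (log2 2.38) and Mthfd2 at 2045 ± 1586 against 164.8 ± 17 (log2 3.04). The number called was 1342 probe sets, 560 higher and 782 lower, for 1063 genes.

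Of 22 proliferation genes 0 were higher and 7 lower (0 and 9 adjusted over the list alone; adjusted p = 4.5e-06, and adjusted p = 0.267 with an estimated correlation), Pcna at -1.04, Mcm6 at -1.76 and Mki67 at -1.39. FoxO targets had 3 higher and 0 lower of 20 (6 and 0 adjusted over the list alone; adjusted p = 0.000726, and adjusted p = 0.0525 with an estimated correlation), Klf15 at 1.30, Gabarapl1 at 0.81 and Bnip3, a mitophagy receptor, at 0.54. Natriuretic and wall stress genes had 3 and 0 of 8 (6 and 0 adjusted over the list alone; adjusted p = 2.91e-05, and adjusted p = 0.0525 with an estimated correlation), Lcn2 at 1.36, Ccn2 at 1.30 and Ace at 0.75. The hypertrophy and fetal list had 4 and 0 of 10 (5 and 1 adjusted over the list alone; adjusted p = 0.006, and adjusted p = 0.539 with an estimated correlation), with Fhl1, a titin-binding protein, at 0.81 and Ankrd1 at 0.71.

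Endothelial markers had 1 higher and 6 lower of 22 (2 and 10 adjusted over the list alone; adjusted p = 0.00613, and adjusted p = 0.683 with an estimated correlation). Emcn stood at 522 ± 80.4 against 1235 ± 79.7 (log2 -1.17), Kdr, the main receptor of Vegfa, at -0.84 and Pecam1 at -0.91. Oxidative phosphorylation had 0 and 6 of 54 (0 and 10 adjusted over the list alone; adjusted p = 2.91e-05, and adjusted p = 0.683 with an estimated correlation), with Uqcrfs1 of complex III at -0.53 and Sdhc at -0.68. The tricarboxylic acid cycle list had 0 and 3 of 16 (0 and 5 adjusted over the list alone; adjusted p = 0.0406, and adjusted p = 0.683 with an estimated correlation), Suclg1 at -0.63 and Dlat at -0.53, a call that ended with arrays scaled to a common median (adjusted p = 0.0938), with the Actb ratio as a covariate (0.0764), without heart 2 (0.214) or heart 3 (0.163) at 6 weeks and without heart 2 (0.0848) or heart 3 (0.0587) at 2 weeks. The regulator of fatty acid genes Ppara was higher by 1.15. Vegfa was lower by log2 -0.66 and Vegfd higher by 1.44, in an angiogenic list with 1 higher and 4 lower of 14 (2 and 5 adjusted over the list alone; list adjusted p = 0.365).

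Further genes with large differences were the metallothionein Mt2 at 2.91, Ints6 at 2.53, Thbs4 at 2.36, the kinesin Kif1c at 2.21 and, on chip 430B, Fam107a at 2.26 and Enkur at 2.15. Lower at 6 weeks were the class I antigen H2-D1 at -2.16, D17H6S56E-5 at -1.91, the apelin receptor Aplnr at -1.86, Abcc9 at -1.84, Ttll1 at -1.77 and, on chip 430B, the urate transporter Slc2a9 at -2.33 and Nxpe4 at -2.15. The count fell to 730 without heart 2, to 739 without heart 3 at 2 weeks and to 730 without heart 1 at 6 weeks. Arrays scaled to a common median gave 624 higher and 546 lower, a share higher of 53.3% against 41.7%. The fatty acid and immediate early lists were called without the filter (adjusted p = 0.0468 and 0.0437), without heart 4 at 2 weeks (0.0152 and 0.0025) and without heart 1 at 6 weeks (0.0215 and 0.0156), and the immediate early list with the replicate block (0.0294). Other splits called up to 186 probe sets and up to 11 lists against 7 for the real one.

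**Figure D3:**
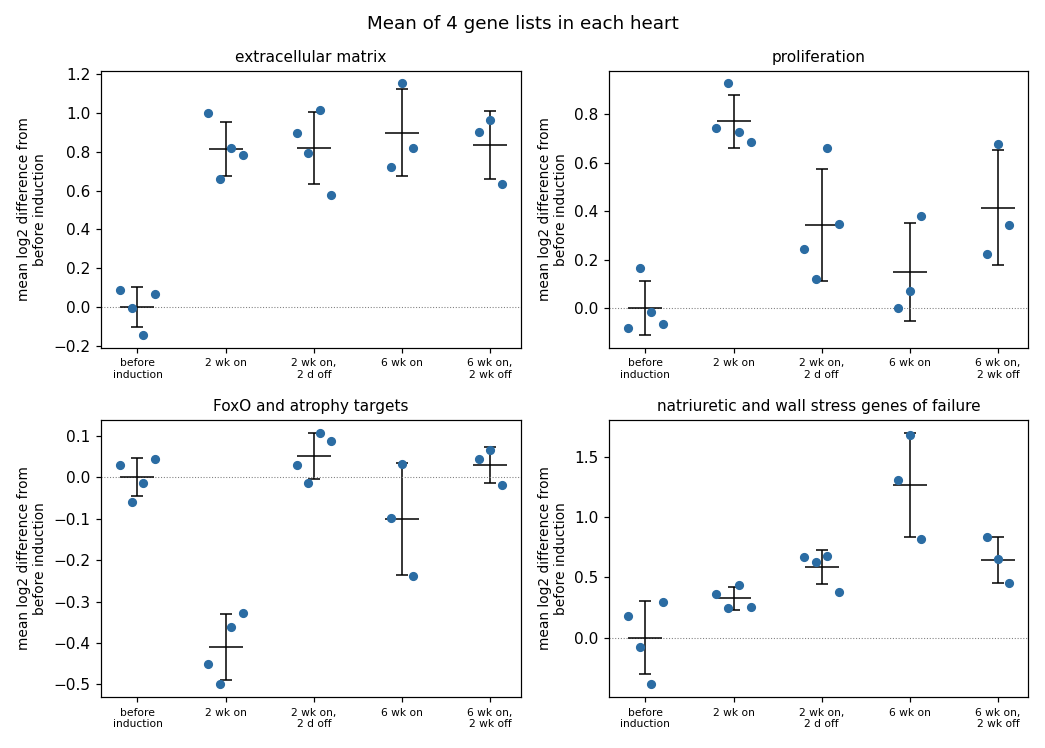
Mean log2 difference from the hearts before induction of 4 gene lists in each heart (points), with the group mean and SD. The matrix list stands near 0.8 to 0.9 in all 4 later groups. The natriuretic and wall stress list is highest at 6 weeks on, with a mean of 1.27. Its natriuretic peptide gene Nppb was not called at 6 weeks on against before induction.

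The last main comparison followed repression for 2 weeks after 6 weeks of induction. Akt1 fell from 2365 ± 542 to 753.2 ± 107 (SD, n = 3 each; log2 -1.57, adjusted p = 3.19e-05). Of 16 genes of the tricarboxylic acid cycle 7 rose, a list call that ended with an estimated correlation (adjusted p = 0.435), Vegfa and Irs1 rose, and Ddit4, an inhibitor of mTORC1, fell. Vegfa rose to 1196 ± 34.6 (log2 1.19), Irs1 to 1120 ± 76 (log2 1.48), and Ddit4 fell from 4125 ± 1081 to 268.1 ± 42.4 (log2 -3.69). In all 3605 probe sets were called, 2145 higher and 1460 lower, for 2733 genes.

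The tricarboxylic acid cycle list had 7 higher and 0 lower of 16 (8 and 0 adjusted over the list alone; adjusted p = 0.012, and adjusted p = 0.435 with an estimated correlation), with Suclg2 at 1.19, Dld at 1.08 and Dlat at 0.69. It was the only one of the 26 lists called, and the call ended with arrays scaled to a common median (adjusted p = 0.0582) and without heart 2 at 6 weeks (0.0746). Angiogenic growth factors had 5 higher and 1 lower of 14 (6 and 1 adjusted over the list alone; list adjusted p = 0.0998), Pdgfb at 1.01, Apln at 0.95 and Vegfb at 0.79. Endothelial markers had 6 and 2 of 22 (7 and 3 adjusted over the list alone; list adjusted p = 0.696), Emcn at 1.03 and Pecam1 at 1.12 with Rgcc at -1.62. Oxidative phosphorylation had 6 and 6 of 54 (6 and 7 adjusted over the list alone), with Ndufs1 at 0.87 and Sdha at 0.60. FoxO targets had 4 and 1 of 20 (5 and 2 adjusted over the list alone; list adjusted p = 0.696), Trim63 at 1.26 and Gabarapl1 at 0.91, and the natriuretic list 0 and 3 of 8 (0 and 3 adjusted over the list alone; list adjusted p = 0.0988), Agt at -2.04 and Ace at -0.72. The marker scores of fat and atrium were higher by 1.56 (exact p = 0.2) and 1.35 (exact p = 0.3), and the atrial score ran from -0.86 to 2.35 between the repressed hearts.

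Myh7 had a log2 change of -1.58 and Pdk4 of -2.02. Echs1, an enzyme of fatty acid oxidation, rose by 1.53, Ppargc1a by 0.86 and Myom2 by 2.05. Tgfb2 had a log2 change of -1.70, in a matrix list with 1 gene higher and 1 lower of 30 (0 and 1 adjusted over the list alone; list adjusted p = 0.696). Macrophage markers had 4 higher and 0 lower of 21 (5 and 0 adjusted over the list alone; list adjusted p = 0.108), H2-Eb1 at 0.97 and Lyz2 at 1.15. A dimmer probe set of Gja1 rose by 2.67, the cyclosome subunit Anapc5 by 2.52, Abcc9 by 2.40, Ptp4a2 by 2.37 with another of its probe sets called lower, Glg1 by 2.31, β-catenin, Ctnnb1, by 2.30 and Orai3 by 2.94. Psmd6 had a log2 change of -3.36, Resf1 of -3.08, Mthfd2 of -2.84, Cdkn1a of -2.74, Gadd45g of -2.50 and, on chip 430B, Ptprg of -3.13 and Pih1d1 of -3.00.

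Of the 4361 probe sets called at 6 weeks, 2090 (47.9%) were reversed, 1289 of them lower at 6 weeks, Vegfa and Irs1 included, and 801 higher, Cdkn1a and Mthfd2 included. Independent lists would share 82.4 of those higher and 162 of those lower. The same 6-week hearts stood in both comparisons, and a group of 3 was not divided. For groups with no change, 50 simulations gave a mean reversed count of 0. Without a change there are almost no calls to reverse, so that count cannot show what the shared hearts contribute. The log2 changes on the A chip had a correlation of -0.747, against a mean of -0.534 in those simulations. Shared hearts alone set a correlation near that mean, so it does not measure their part. The covariance of the changes was -0.1828, against a mean of -0.0281 in the simulations. How many of the 2090 calls rest on the shared hearts was not settled, as the covariance concerns all probe sets of that chip. Of the 4361, 341 (7.82%) were still called with the same sign against the hearts before induction. Without heart 3 at 6 weeks 2221 probe sets were called and 1269 reversed, and with the Actb ratio as a covariate 1582 and 1101. The number reversed was 1132 without the hearts with Xist signal, 1259 with an Xist indicator, 598 with only the arrays of the groups compared and 497 with a minimum of 2-fold. Other splits of these 6 hearts called up to 33 probe sets and up to 9 lists, against 1 for the real one. Arrays scaled to a common median gave 1651 higher and 1814 lower, a share higher of 47.6% against 59.5%. The angiogenic and natriuretic lists were called with the Actb ratio as a covariate (adjusted p = 0.00203 each) and without heart 3 at 6 weeks (0.0118 and 0.00477). The macrophage list was called without heart 1 at 6 weeks (0.0102) or heart 3 of the repressed group (0.0121), and the adipocyte list without the latter (0.0121).

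Hearts at 2 weeks off were also set against those before induction. The matrix list was higher here too, with 15 genes higher and 0 lower of 30 (27 and 0 adjusted over the list alone; adjusted p = 6.38e-24, and adjusted p = 0.0411 with an estimated correlation). Postn stood at 3975 ± 908 (SD, n = 3) against 695 ± 206 (SD, n = 4; log2 2.45, adjusted p = 6.36e-06), Timp1 was higher by 2.13 and Bgn, the proteoglycan biglycan, by 0.67. Akt1 did not pass (log2 0.42, adjusted p = 0.191). Ryr2, by its brightest probe set, was higher by 1.19, Mcm6 by 1.73, and Gsn, gelsolin, had a log2 change of -1.05. The number called was 851 probe sets, 387 higher and 464 lower, for 642 genes.

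Oxidative phosphorylation had 0 higher and 5 lower of 54 (0 and 7 adjusted over the list alone; adjusted p = 1.05e-08, and adjusted p = 0.581 with an estimated correlation; 0.0619 with quantile normalization), Ndufb10 at -0.86. Macrophage markers had 0 and 0 of 21 (1 and 0 adjusted over the list alone; adjusted p = 0.000158, and adjusted p = 0.549 with an estimated correlation), proliferation 2 and 0 of 22 (5 and 0 adjusted over the list alone; adjusted p = 0.000939, and adjusted p = 0.549 with an estimated correlation), and the natriuretic list 1 and 0 of 8 (2 and 0 adjusted over the list alone; adjusted p = 0.0121, and adjusted p = 0.347 with an estimated correlation). The adipocyte list, with 1 and 0 of 6 (1 and 0 adjusted over the list alone), had an adjusted p of 0.0362, and adjusted p = 0.614 with an estimated correlation. The proliferation call ended with the filter at 50% of the trimmed mean (0.183) and without heart 2 of the repressed group (0.0559). The natriuretic call ended with an Xist indicator (0.0545), with the Actb ratio as a covariate (0.0601) and without heart 3 before induction (0.0612). The adipocyte call ended without an offset (0.0784), with the 50% filter (0.147), the replicate block (0.0582) or the Actb ratio (0.0601), without hearts 1, 2 or 3 before induction (0.0852, 0.07 and 0.066) and without heart 2 of the repressed group (0.517).

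Further lists were called with other settings. The sarcomere, endothelial, atrial and translation lists were called without the hearts with Xist signal (adjusted p = 0.00247, 0.0416, 0.00599 and 0.0226) and with an Xist indicator (0.00193, 0.0448, 0.0178 and 0.0247). The sarcomere list was also called without heart 2 (0.0383), 3 (0.0474) or 4 (0.0189) before induction, heart 1 at 2 weeks on (0.0368) or heart 3 of the repressed group (0.00993), and the atrial (0.0141) and translation (0.0398) lists without heart 4 before induction. The hypertrophy and fetal list was called with quantile normalization (0.0317), without the filter (0.0254), and without heart 1 (0.00255) or 4 (0.0489) before induction, heart 2 (0.0487) or 3 (0.0459) at 6 weeks or heart 3 of the repressed group (0.00372). Quantile normalization added the tricarboxylic acid cycle and glycolysis lists (0.0317 each), and the fatty acid list was called without heart 2 before induction (0.0497) or heart 3 of the repressed group (0.0314).

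The count of 851 fell to 482 and 436 without hearts 2 and 3 before induction, and to 366 and 479 without hearts 1 and 3 of the repressed group. It was 276 without the hearts with Xist signal, where leaving out other pairs gave 125 to 547. Arrays scaled to a common median gave 402 higher and 328 lower, a share higher of 55.1% against 45.5%, and other splits called up to 197 probe sets and up to 12 lists against 6 for the real one.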

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

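The tests of Y-linked signals, of mixed RNA and of age were chosen only after the results were seen, as were the model alternatives without hearts 3 and 4, with an Xist indicator and with the Actb ratio. The test of 18S signal and the division of the hearts before induction were added after the patterns were seen and before their own results were, and the ranges with a heart left out after the results they accompany.

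Hearts 3 and 4 before induction carried Xist, the transcript of the inactive X chromosome, with signals of 2518 and 2170 for 1 probe set and of 5412 and 3271 for another, against at most 92.8 and 289.2 in the other 16 hearts. In both hearts all 3 Y-linked probe sets tested, of Eif2s3y, Kdm5d and Uty, lay below all 16 others, so these hearts may come from female mice although the labels say male. A mixture of male and female RNA is argued against, because the higher Eif2s3y signal of the pair was 0.688% of the median of the others. The median signed change of the 2-week calls against hearts 1 and 2 was 90.9% of that against hearts 3 and 4. These probe sets were called with all 4 hearts, which favours those alike in both pairs. The share therefore cannot decide whether calls rest on the sex of the pair. Without the pair 524 probe sets were called, where leaving out other pairs gave 465 to 1038. Which hearts the labels should name, and whether sex changes single genes here, stays open.

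In heart 3 at 6 weeks on the Actb 3′ to 5′ ratio was 3.707 on chip 430A and 4.204 on chip 430B, and the Gapdh ratio 1.539 and 1.527, above the hearts before induction. Degraded RNA in that heart could shape the 6-week calls. Without it their median signed change kept 91.9% of its size (0.705 against 0.767). These probe sets were called with that heart, by a test that disfavours changes of a single heart, so this share cannot decide. The fit without it called 3111 probe sets, 2585 of them among the 4361. With the Actb ratio as a covariate 92.8% remained (87.4% to 101% with a heart left out). These probe sets were called without the covariate, by a test that disfavours those that follow the ratio within a group. This share therefore cannot decide on a 3′ bias either. Hearts 1 and 2 at 6 weeks had ratios of 1.358 and 1.236 on chip 430A, within the 1.212 to 1.607 before induction. The 2585 calls kept without heart 3 therefore did not need a high ratio. With the 18S signal 105% remained (92.9% to 110%). That signal did not overlap between the groups compared. It raised the median standard error from 0.184 to 0.341, so that 348 of the 4361 calls were left. That fit therefore cannot decide on a difference in 18S ribosomal RNA signal. Age as the whole cause is argued against, because the repressed hearts, 2 weeks older, had 24.6% of the median signed change over the same probe sets (0.188 against 0.767, and 21.2% to 27.6% with a repressed heart left out). These values concern the calls as a set, and an effect of Akt1 that depends on age, or of age on single genes, stays open as untested.

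Both repressed groups shared 114 probe sets, 54 higher and 60 lower, that stood apart from the hearts before induction and from the induced hearts, among them Tuba4a, Psmd6 and Arhgap26, and 20 to 26 with the hearts before induction divided between them in 6 ways (at most 0.513 for independent lists) and 50 without hearts 3 and 4. With the Actb ratio as a covariate 89.0% of the median signed change remained (0.678 against 0.762, and 86.6% to 92% with a heart left out). These probe sets were chosen by calls without the covariate, and the ratio did not overlap between 2 days off and before induction. This share therefore cannot decide on RNA integrity. With the 18S signal 92.8% remained (83.6% to 109%). On chip 430A that signal did not overlap between the repressed hearts and those before induction. It raised the median standard error from 0.17 to 0.28, which left 2 of the 114. That fit therefore cannot decide on a difference in 18S signal. The time of day at which hearts were taken may contribute, as 7 of 13 clock genes (53.8%, against 1.88% of all genes) were called the same way in both repressed groups, with Dbp at log2 -2.32 and -1.94 and Arntl at 1.37 and 1.59, though clock genes were also called in the induced groups. Differences in hybridisation of single probe sets cannot be told apart from changes of the genes, since the other probe sets of the same genes moved by 29.2% as much, 126 of 171 with the same sign. A lasting response of the hearts to the repression itself stays open as an untested biological explanation.

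The change on repression differed by an interaction test between the 2-week and the 6-week induction for 155 probe sets, 78 with the larger value after 6 weeks and 77 with the smaller. The change of Abcc9 (1.97), Mcm6 (2.70) and Emcn (1.07) was the more positive after 6 weeks, and that of Ddit4 (-2.55), Mthfd2 (-3.26), Ints6 (-2.48) and Cdkn1a (-2.45) the more negative, in log2 units. Mcm6 fell on repression after 2 weeks (log2 -1.87), and 23 of the 155 probe sets had opposite calls in the 2 repressions. The repressions also differed in length, 2 days and 2 weeks, so the difference cannot be put to the time of induction alone.

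At 2 weeks on, heart 1 had Actb ratios of 1.922 and 1.875 on chips 430A and 430B and Gapdh ratios of 1.111 and 1.107, and heart 4 a Gapdh ratio of 0.9432 on chip 430B, above the hearts before induction.

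In 36 of 468 groups of 4 values a single heart lay far from the other 3, where chance gives about 1 in 20. Before induction these were heart 1 for Tubb6 (169.8), Thbs4 (188.9), Aplnr (1174), Nxpe4 (41.89) and Pi16 (994.2), heart 2 for Sh3gl3 (167.6), heart 3 for Alas2 (675.2), Kcnq1 (823.9) and Slc27a1 (724), and heart 4 for Akt1 (652.2), Mfap5 (1767) and Ttll1 (3430), in units of signal. At 2 weeks on they were heart 1 for Ankrd1 (10360), Myh7 (1456), Col4a4 (313.1), Cspg4 (628.6), Sdha (5544) and Tcap (21700), heart 2 for Gnb3 (224.6), Arhgap26 (39.83), Cdk1 (490.3) and Kif1c (301.1), heart 3 for Gadd45g (216.7), Anapc5 (729.1) and Slc2a9 (101), and heart 4 for Tubb4b (4216). At 2 days off they were heart 2 for Gnb3 (180.3), heart 3 for Tubb6 (103.3), Aplnr (1043), Fasn (3628), Kcnj5 (189), Nxpe4 (50.25) and Slc2a9 (367.9), and heart 4 for Tubb4b (1178), Ankrd1 (17170) and the score of the natriuretic list (0.3754).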

How the results depend on the processing

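The alternatives without hearts 3 and 4, with an Xist indicator and with the Actb ratio, and for the lists the 50% filter and the 20% offset, were chosen after the data were seen; the causes of the differences below were not tested, except that a 2-fold minimum leaves fewer calls by construction. Comparisons are given in the order 2 weeks on, 2 days off against on, 2 days off against before, 6 weeks on, 6 against 2 weeks on, 2 weeks off against on, and 2 weeks off against before. Called probe sets in that order were 404, 662, 268, 1219, 385, 1147 and 330 at 2-fold or more, with 139 and 497 reversed and 227 shared. Array weights gave 3196, 6019 and 2617 for the first 3 and 1298 for the last, with 1900 reversed after 2 days and 1601 shared. Only the arrays of the 2 groups gave 1698, 2351, 360, 933 and 370 for the last 5, with 598 reversed after 2 weeks, and no trend gave 560 for the last. Without hearts 3 and 4 the comparisons with before induction gave 524, 509, 2115 and 276, with 275 and 1132 reversed and 349 shared, and the Xist indicator gave 561, 560, 2291 and 301, with 303 and 1259 reversed and 368 shared. With the Actb ratio 2 weeks off against on gave 1582, with 1101 reversed.

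Called lists with an estimated correlation were 0, 0, 1, 0, 0, 0 and 1, and fry gave 6 at 2 weeks on, 2 at 2 days off against before, 9 at 6 weeks on, and 4 and 2 for the last 2 comparisons. Scaling to a common median gave 3 lists at 6 weeks on and 0 at 2 weeks off against on, the Actb ratio gave 6 at 2 days off against before and 3 at 2 weeks off against on, and leaving out hearts 3 and 4 gave 10 at 2 weeks off against before. The filter at 50% of the trimmed mean gave 6 lists, against 10, at 2 days off against before.

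Leaving out each heart in turn gave 1019 to 1792, 2271 to 3108, 502 to 1054, 3111 to 4494, 730 to 1347, 2221 to 3456 and 366 to 881 probe sets, and 3 to 5, 3 to 8, 6 to 11, 2 to 5, 6 to 9, 0 to 3 and 4 to 10 lists. Reversed calls ranged from 477 to 889 and from 1269 to 2121, and shared calls from 648 to 1165. The other values, among them those with changed offsets, no filter, quantile normalization and the replicate block, stayed within 1.5 times of the main counts. For 458 changes of named genes, 8467 of 9667 alternatives kept direction and side of the threshold, 1193 lost the call, 7 gained one and 0 turned. On chip 430B, where signals lie lower, simulated changes of 1 log2 unit were recovered in 22.4% to 47.8%, with 200 changed probe sets per chip. As far as that setting resembles the data, missing calls there say little.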

Other observations

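The tests of all splits of the hearts were chosen before the results were seen; the clock genes were listed only after repressed hearts had been seen to stand apart.

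Clock genes differed in several groups from the hearts before induction. Dbp, Hlf and Ciart, outputs and repressors of the circadian clock, had log2 changes of -2.32, -1.19 and -2.15 at 2 days off and of -1.94, -1.49 and -1.68 at 2 weeks off. Per1, Per2 and Per3 were lower as well, by -1.13, -0.84 and -1.15 and by -1.04, -1.13 and -1.13. Hlf, Per3, Nr1d1, Nr1d2 and Cry2 were called lower in both induced groups, at -0.90, -0.87, -0.42, -0.60 and -0.96 at 2 weeks and -0.95, -0.86, -0.83, -0.88 and -1.42 at 6 weeks. Ciart (-1.51) and Tef (-0.59) were lower at 2 weeks on, and at 6 weeks on Dbp was lower (-1.04) and Arntl higher (1.03). The hour of sampling is not given in the sources used here. A difference in that hour could therefore also enter the comparisons of the induced groups with the hearts before induction. This was not tested.

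Each comparison was repeated for the other splits of the same hearts. For the comparisons other than 2 weeks off against 6 weeks on, 1 of 35 splits, the real one, gave as many called probe sets. That share is under 0.05 for each of those 6 counts taken alone. It is also the smallest that 35 splits allow and was not adjusted over the comparisons, so it does not exclude chance. The real and the highest other counts were 1658 and 357 at 2 weeks on, 3219 and 2 at 2 days off against on, 1069 and 2 at 2 days off against before, 4361 and 2100 at 6 weeks on, 1342 and 186 at 6 against 2 weeks on, and 851 and 197 at 2 weeks off against before. The splits with 357, 2100, 186 and 197 kept most hearts with their own group, so those counts are not a level without any group difference. For 2 weeks off against 6 weeks on the 10 splits are too few for a share under 0.05, and the values were 3605 and 33.

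For the numbers of called gene lists chance was not excluded in 6 comparisons. As many lists were called by 26 of 35 splits at 2 weeks on (real 3, highest other 10), 21 at 2 days off against on (5 and 10), 2 at 2 days off against before (10 and 10), 15 at 6 weeks on (5 and 12), 13 at 6 against 2 weeks on (7 and 11) and 16 at 2 weeks off against before (6 and 12). For 2 weeks off against 6 weeks on 10 of 10 splits called as many, with 1 list in the real split and 9 in the highest other, and those splits are too few for a share under 0.05.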
